A study of Mus musculus with 4 samples.

How the data were processed

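RNA was measured by poly(A) RNA sequencing in group 1 innate lymphoid cells (ILC1) sorted from the liver of C57BL/6 mice. Per the labels, the sorted cells were positive for CD45.2, NKp46, NK1.1 and CD49a and negative for CD3, CD19 and CD49b. The 4 libraries fall into 2 groups, 3 wild-type libraries (WT replicates 1 to 3) and 1 library labelled cKO, in which the gene Rora was to be removed by a Cre recombinase driven from the Ncr1 locus. Cells were lysed in TRIZOL, RNA was purified on Direct-zol columns, and libraries were made with a NEBNext Ultra kit, per the labels' protocols. Nothing in the labels says whether the 3 WT libraries came from separate animals, so the p-values measure the spread between these libraries, which may be technical. The labels do not give the sex, the age or the number of mice per library.

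HISAT2 2.0.5, featureCounts 1.5.0-p3, edgeR 3.34.1 and the mouse build GRCm38 are named in the submitters' processing notes, with no order or settings. The annotation release, the strand setting of the counting and the filter on genes are not given in the sources used here. Where genes overlap, or where a gene has an antisense partner, the reads cannot be assigned with certainty. The deposited table lists 10536 genes with a signal for each library, a normalised read count that the authors scaled to a common library size. The values are not divided by gene length. Its other columns hold the authors' log2 fold change of cKO over WT, their log2 mean CPM, a p-value and its adjusted value, per the file headers. The ratio of adjusted to raw p at the top of the authors' deposited table corresponds to about 15086 genes tested, more than the 10536 listed, and the lowest log2 mean CPM listed was 0.46. Genes below that level were not analysed here. In 15 rows the gene name had been turned into a date, and these rows are not named in the text.

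The deposited values are not whole. Each library's values were inverted to reads by undoing a quantile adjustment of counts to a common library size with 1 dispersion for all genes, a form inferred from the values. The dispersion that gave whole reads was 0.0123. Of values under 300, 100% lay within 0.1 of a whole read in every library, and of all values 98.9% to 99.96%. On simulated counts the inversion returned 100% of 10536 genes to within 0.1% of their reads. The reads in listed genes came to 34850606, 33626252 and 34268304 in WT replicates 1, 2 and 3 and 42533599 in the library labelled cKO. A single read was worth 1.10, 1.17, 1.08 and 0.715 normalised counts in these libraries. Where a gene had 0 reads in the library labelled cKO, a floor of 3 reads in that library, or 2.14 normalised counts, gives the bound on the fold. Intervals (95%) and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Each pair of WT libraries differed by more than counting noise, with a median chi-square per gene 6.49 to 6.98 times its value under counting noise, so the 3 were counted as separate libraries.

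Differences were tested with limma 3.58.1 in R 4.3.3 on log2(normalised count + 1), with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. A minimum mean of 1 was set, which removed 0 genes. Log2 differences are the library labelled cKO minus the WT mean on this scale, which understates the change of low genes, while folds are ratios of normalised counts. The fit leaves 2 residual degrees of freedom per gene, moderated across genes. The single cKO library has no spread of its own and is assumed to vary like the WT libraries. An exact permutation test of 1 library against 3 cannot give a p below 0.25. On counts simulated for this comparison over 10536 genes, with 50 genes at each fold, limma called 54% of genes changed 1.5-fold, 94% at 2-fold and 100% at 4-fold and 8-fold, and 7 of 10336 unchanged genes. The simulation gave all genes 1 dispersion (0.0079), the library labelled cKO included, and changed only genes with WT means above 50. Its results are therefore not error rates for the real data.

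A total of 30 gene lists was fixed before the data were examined: ILC1 identity, conventional natural killer (NK) cells, ILC2 and ILC3, cytotoxic effectors, cytokines and chemokines, NK receptors, circadian clock, sterol and lipid synthesis, fatty acid oxidation and PPAR, oxidative phosphorylation, mitochondrially encoded genes, glycolysis and hypoxia, cell cycle, apoptosis, NF-kB and TNF signalling, interferon-stimulated genes, common gamma chain and STAT signalling, TGF-beta signalling, adhesion and migration, immediate early and heat shock genes, ribosomal proteins, and markers of T cells, B and plasma cells, Kupffer cells and monocytes, neutrophils and mast cells, dendritic cells, hepatocytes, endothelial and stellate cells, erythroid cells and platelets, and sex. The 28 lists with 5 or more measured members were tested with camera (limma) at a preset correlation of 0.01 and again with the correlation estimated from the residuals. With the estimated correlation, the test relies on the 2 residual degrees of freedom of the fit, so few lists can pass it. The list medians were ranked among 10000 random lists matched on mean level. Genes named in the text were chosen by a rule fixed at the same time. It took Rora, then the 12 higher and 12 lower genes with the largest log2 differences among those past the threshold, at 5 or more normalised counts in the higher group and outside the WT range, leaving out predicted genes, clones, pseudogenes marked as such in their symbol and receptor segments. Up to 4 members of each list followed. Other named genes are said to have been chosen after their values were seen. No column of per-library values was left unused.

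Gene positions, transcript lengths and GC contents come from the GENCODE vM21 annotation of GRCm38, in which 10344 of the 10536 symbols were found and 10340 had a length. Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a mean of at least 5, median-of-ratios, trimmed-mean and quantile scaling, no variance trend or a robust one, each WT library left out, and the estimated correlation. A mean of at least 500, voom (limma) on the recovered reads, removal of trends with transcript length and GC content by loess with a span of 0.5, and each WT library against the other 2 were added after the data were seen. Python 3.11.15 with scipy 1.17.1 and statsmodels 0.14.6 was used for the remaining steps.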

Results

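The transcriptome of liver ILC1, tissue-resident innate lymphocytes that make interferon gamma and express the NK cell receptors NKp46 and NK1.1, was compared between 3 WT libraries and 1 library labelled cKO. The design text asks which genes differ in ILC1 after conditional removal of Rora, the gene of the nuclear receptor ROR alpha, in cells that express Ncr1. Reads in the 10536 listed genes came to 34850606, 33626252 and 34268304 in WT replicates 1 to 3 and to 42533599 in the library labelled cKO. Across genes, the log2 values of WT pairs correlated with r between 0.992 and 0.993, and those of the library labelled cKO with each WT library with r between 0.912 and 0.916. The median coefficient of variation among the WT libraries was 8.18%.

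Rora, on chromosome 9 from 68653786 to 69388246 (GRCm38, plus strand), was not lower in the library labelled cKO. Its normalised read counts were 1643, 1598 and 1477 in WT replicates 1, 2 and 3 (mean 1573 ± 85.6, SD, n = 3) and 1522 in the library labelled cKO, within the WT range. The log2 difference was -0.046 (SE 0.13; limma, Benjamini-Hochberg adjusted p = 0.776). In the authors' deposited table the log2 fold change of Rora was -0.047, with an adjusted p of 0.817. Removing 1 part of a gene can leave reads from the rest of its transcript, and the labels do not say which exons the floxed allele loses, so the gene total does not check the label. With the trend on transcript length removed, the difference became -0.72 (limma, Benjamini-Hochberg adjusted p = 6.71e-06), and under quantile normalization it was 0.017. For these reasons the library is called the library labelled cKO throughout, and every direction below is that of this library against WT.

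Many genes of ILC1 differed between the library labelled cKO and WT. Cd8a, which encodes a coreceptor chain best known from CD8 T cells, rose 17.1-fold, from 333 ± 18.8 (SD, n = 3) to 5692 normalised counts. Klra8 and Klra10, which encode NK receptors of the Ly49 family, rose 8.48-fold and 8.90-fold. Tmem176b and Tmem176a, a pair of neighbouring membrane protein genes on chromosome 6 counted among the ILC1 identity genes, fell 22.7-fold and 31.5-fold, from 10979.6 ± 606 to 484 and from 4696 ± 443 to 149 (SD, n = 3). The keratin gene Krt83 fell 57.0-fold, from 1545 ± 126 (SD, n = 3) to 27.1.

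Limma called 6527 of the 10536 genes at a Benjamini-Hochberg adjusted p under 0.05, 3151 higher and 3376 lower. Of these, 2246 differed at least 2-fold (1051 higher, 1195 lower) and 332 at least 4-fold (116 higher, 216 lower). The library labelled cKO lay outside the WT range for 86.8% of genes, where chance gives 50%. The authors' deposited table lists 6231 genes at an adjusted p under 0.05, 3063 higher and 3168 lower, of which 6205 were also called by limma, 100% of them in the same direction. With a single library labelled cKO, these p-values compare that library with the spread of the WT libraries and cannot separate genotype from anything else that set this library apart.

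Among the other genes with the largest increases, Lars2, listed as the mitochondrial leucyl-tRNA synthetase, went from 272 ± 88.7 (SD, n = 3) to 11416, or 42.0-fold, and Adgrl1, an adhesion receptor gene, from 328 ± 36.8 to 2795, or 8.51-fold. Whether the reads of Lars2 came from its own transcript was not tested. Sva had 9 reads in the 3 WT libraries together and 405 in the library labelled cKO, with a log2 difference of 6.67 (SE 1.10). Most of its WT signal was in replicate 3 (8.44 normalised counts, against 1.20 and 0.12 in replicates 1 and 2). Pde1b, a phosphodiesterase gene, rose 12.6-fold, Rgs11, a regulator of G protein signalling, 10.2-fold, Grk3 7.67-fold, Dancr 7.51-fold, Lgals4 7.36-fold and Ptpn5 7.11-fold. The fold of Ptpn5 depends on WT replicate 3, as its WT values were 13.5, 9.98 and 36.2 in replicates 1, 2 and 3. Only 8 genes had 0 reads in the library labelled cKO. Against the floor of 3 reads in that library, Igha was at least 99.0-fold lower, Xist at least 61.0-fold, Jchain at least 59.2-fold, Thsd7b at least 54.3-fold, Upp1 at least 43.2-fold, Fam124b at least 41.7-fold, Ighg2b at least 34.5-fold and Qrfp at least 32.0-fold. Igha, Jchain and Ighg2b are antibody genes of B and plasma cells. Serpinb1a, a protease inhibitor gene, fell 91.2-fold, the leukotriene B4 receptor gene Ltb4r1 87.2-fold and the kinase gene Nuak2 58.0-fold, each to 6 reads or fewer in the library labelled cKO.

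Genes that set ILC1 apart were lower in larger number than higher. Of 24 measured ILC1 identity genes 15 fell and 5 rose, both over all genes and adjusted over the list alone, with a median log2 difference of -0.53. The largest decreases after the Tmem176 pair were Il7r, the receptor for interleukin 7, which fell 7.50-fold from 1806 ± 149 to 241, and Cd160, a receptor gene, which fell 5.10-fold from 86702 ± 3656 (SD, n = 3). Runx3 and Prdm1, transcription factors of tissue-resident lymphocytes, rose by 1.47 and 1.21 on the log2 scale, and the gate gene Itga1 (CD49a) by 0.86; these 3 were picked after their values were seen, as were Tbx21 and Eomes. Tbx21, the transcription factor T-bet, was 21225 ± 905 in WT (SD, n = 3) and 15108 in the library labelled cKO, and Eomes, its relative in conventional NK cells, 91.6 ± 19.9 and 231. The test across lists called ILC1 identity genes lower (camera, Benjamini-Hochberg adjusted p = 0.00297; adjusted p = 0.591 with an estimated correlation). Their median ranked at 10.7% of the random lists matched on mean level, so by that measure it was not unusual.

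**Figure D1:**
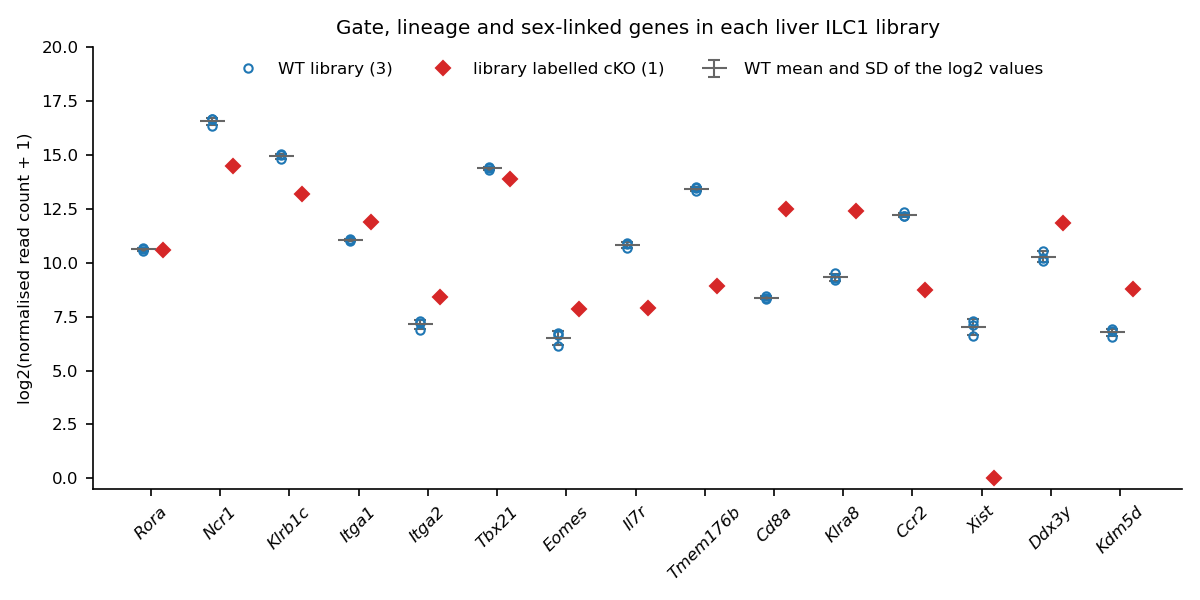
Normalised read counts, as log2(count + 1) on the vertical axis, of 15 genes in each library. Open circles are the 3 WT libraries with their mean and SD, and the diamond is the library labelled cKO. Rora lies within the WT range (1522 against 1477 to 1643), Cd8a and Klra8 lie above it, Tmem176b, Il7r and Ccr2 below it, and Xist is at 0 reads.

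Genes of conventional NK cells, the circulating relatives of ILC1, moved in both directions. Of 18 measured, 7 rose and 8 fell (7 and 9 adjusted over the list alone), with a median of -0.44 and no call for the list (camera, Benjamini-Hochberg adjusted p = 0.815). Besides Klra8, Klra4 rose 4.72-fold, whereas the chemokine receptor gene Ccr2 fell 11.2-fold, from 4813 ± 308 (SD, n = 3) to 430. Sell, which encodes L-selectin, had 1 read in the library labelled cKO, a ratio of WT to cKO of 99.7 with a counting interval of 17.2 to 3794. The 10 measured genes of ILC2 and ILC3 included 5 lower and 2 higher ones (5 and 3 adjusted over the list alone; median -0.51; camera, Benjamini-Hochberg adjusted p = 0.379). Areg, which encodes the growth factor amphiregulin, fell 25.6-fold, Kit 3.01-fold and Klrg1 2.33-fold, and Id2, a transcription regulator that all innate lymphoid cells need, fell 1.62-fold.

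NK receptors fell as a list. Of 21 measured, 16 fell and 3 rose (17 and 3 adjusted over the list alone), with a median of -0.77 (camera, Benjamini-Hochberg adjusted p = 0.000141; adjusted p = 0.591 with an estimated correlation). Klrc1, the inhibitory receptor NKG2A, fell 9.80-fold from 98356 ± 17559 (SD, n = 3) to 10037, and Klrb1b 9.61-fold. Genes of 2 markers of the sort gate fell, Ncr1 (NKp46) 4.16-fold from 96236 ± 11044 to 23124 and Klrb1c (NK1.1) 3.43-fold from 31431 ± 2498 to 9164 (SD, n = 3). The Cre of the design is driven from the Ncr1 locus, and whether that altered the reads of Ncr1 was not tested. The Klr genes lie together in the NK gene complex on chromosome 6. There, 10 of 11 measured Klra genes and pseudogenes rose and 0 fell, with a median log2 difference of 2.03, while 5 of 8 Klrb1 and Klrc genes fell and 3 rose, with a median of -1.32. Of the Klra genes, the NK receptor list holds only Klra1 and Klra7, so the fall of the list does not extend to this family. Klra genes are near-identical copies whose reads can be exchanged, so their single values are uncertain, but the sum over the 11 was 37994 ± 1738 (SD, n = 3) in WT and 120413 in the library labelled cKO, 3.17-fold higher.

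**Figure D2:**
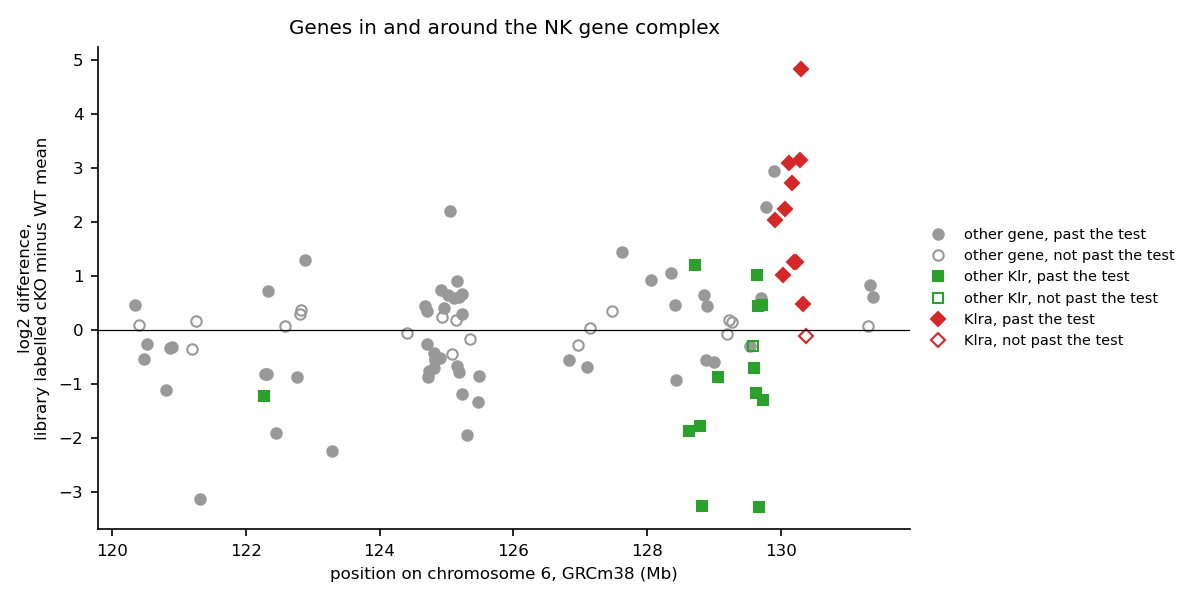
Log2 difference (library labelled cKO minus WT mean, vertical axis) of genes in and around the NK gene complex, by position on chromosome 6 in Mb (GRCm38). Filled symbols passed the limma test. The 11 Klra genes have a median of 2.03, and Klrc1 (-3.28) and Klrb1b (-3.26) are the lowest Klr genes.

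Genes of cytotoxic granules were called lower as a list (camera, Benjamini-Hochberg adjusted p = 0.00308), but not with an estimated correlation (adjusted p = 0.591) or under quantile normalization (adjusted p = 0.0571). Of 16 measured cytotoxic effector genes 10 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.85. The granzymes Gzmc and Gzma fell 3.58-fold and 2.24-fold, the latter from 359289 ± 14057 (SD, n = 3) to 160398, and Serpinb9, an inhibitor of granzyme B, and Srgn, the granule proteoglycan serglycin, fell 3.01-fold and 2.26-fold. Gzmb, the most abundant granzyme gene, and Ctsw, both picked after their values were seen, were not past the threshold, with log2 differences of 0.15 and 0.20 (limma, Benjamini-Hochberg adjusted p = 0.534 and 0.278). Cytokines and chemokines went both ways, 6 of 15 higher and 5 lower, also adjusted over the list alone. Their median was 0.14, their mean -0.13 and the direction of the test was down (camera, Benjamini-Hochberg adjusted p = 0.933). The chemokine gene Xcl1 fell 4.63-fold, Tnfsf14 2.67-fold and Ltb 1.97-fold, and Flt3l, a growth factor for dendritic cells, rose 2.02-fold.

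Receptors for cytokines and for homing were also among the genes that fell. In the common gamma chain and STAT list 9 of 20 genes fell and 3 rose, also adjusted over the list alone. Il18r1, a chain of the interleukin 18 receptor, fell 9.03-fold, Il2ra 7.80-fold and Socs3, a feedback inhibitor of cytokine signalling, 4.40-fold. That list was not called (median -0.17; camera, Benjamini-Hochberg adjusted p = 0.110), except without WT replicate 3 (adjusted p = 0.0257). Of 16 adhesion and migration genes 12 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -0.91 (camera, Benjamini-Hochberg adjusted p = 0.00120; adjusted p = 0.591 with an estimated correlation). Ccr7 fell 5.62-fold and Cd53 4.84-fold, and Itga4, the integrin alpha 4 chain, rose 3.37-fold. In the TGF-beta list 6 of 14 rose and 5 fell, also adjusted over the list alone (median 0.24; camera, Benjamini-Hochberg adjusted p = 0.415), with Ctla2a up 5.46-fold, the receptor gene Tgfbr1 up 2.64-fold and Itgav up 2.42-fold, and Cd9 down 2.53-fold.

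Stress and survival genes were mixed. Of 28 immediate early and heat shock genes 14 rose and 5 fell, also adjusted over the list alone, with a median of 0.36. The heat shock genes Hspb1 and Hsph1 rose 5.71-fold and 3.46-fold and the nuclear receptor gene Nr4a2 4.42-fold, whereas Junb, the gene with the largest share of counts in WT, fell 2.93-fold. It was the only list called higher (camera, Benjamini-Hochberg adjusted p = 0.00703; adjusted p = 0.591 with an estimated correlation), and the call was lost without the variance trend (adjusted p = 0.0669). Apoptosis and survival genes gave 7 higher and 10 lower of 23 (median -0.14; camera, Benjamini-Hochberg adjusted p = 0.617), with the survival genes Bcl2a1b and Bcl2a1d down 6.63-fold and 5.97-fold and the pro-apoptotic genes Pmaip1 and Bbc3 up 2.27-fold and 2.14-fold. The Bcl2a1 genes are near-identical copies. NF-kB and TNF genes gave 3 higher and 12 lower of 21 (median -0.28; camera, Benjamini-Hochberg adjusted p = 0.155), with Cd83 down 2.86-fold, Tnfrsf9 down 2.39-fold, and Nfkb1 and Bcl3 up 2.50-fold and 2.47-fold. Interferon-stimulated genes gave 8 higher and 14 lower of 33 (median -0.19; camera, Benjamini-Hochberg adjusted p = 0.379), with Ifi204 down 11.0-fold, Iigp1 4.13-fold, Gbp2 3.45-fold and Isg15 3.12-fold. For these 3 lists the counts were the same adjusted over the list alone.

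Genes of ribosomal proteins, oxidative phosphorylation, and glycolysis and hypoxia were called lower as lists (camera, Benjamini-Hochberg adjusted p = 3.56e-22, 3.35e-11 and 0.00120), but not with an estimated correlation (adjusted p = 0.591 for each). All 31 ribosomal protein genes measured fell, also adjusted over the list alone, with a median log2 difference of -1.53, led by Rps14 (7.72-fold), Rps5 (5.94-fold), Rpl32 (4.94-fold) and Rps3 (4.52-fold). Ribosomal protein genes have many processed pseudogenes that can exchange reads with them. Of 36 oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, 31 fell and 1 rose (32 and 1 adjusted over the list alone), with a median of -0.86, led by Cox7a2 (4.23-fold), Ndufa4 (4.11-fold), Cox4i1 (3.60-fold) and Ndufa2 (3.24-fold). Of 21 glycolysis and hypoxia genes 16 fell and 1 rose, also adjusted over the list alone, with a median of -0.56. Egln3 fell 3.57-fold, Vegfa 3.01-fold, Ldha, the lactate dehydrogenase gene, 2.89-fold and Slc16a3, a lactate exporter gene, 2.68-fold.

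Signs of RNA makeup moved together with these groups. The log2 difference followed transcript length. In the shortest of 10 equal bins of transcripts, 12 to 1138 nt, the median was -0.64 and 57.8% of genes fell, and in the longest, 6383 to 123179 nt, it was 0.60 and 59.6% rose. Length accounted for 10.9% of the variance of the log2 difference across genes. With length and GC trends removed, the median was -1.18 for ribosomal proteins, with 28 of 31 lower, and -0.73 for oxidative phosphorylation, with 27 of 35 lower. The nuclear RNAs Neat1 and Malat1 rose 4.15-fold and 2.16-fold, and the small RNA gene Gm23935 rose 16.9-fold, while the small nuclear RNA Rn7sk was not past the threshold (1.14-fold; limma, Benjamini-Hochberg adjusted p = 0.280; genes chosen after their values were seen). Ribosomal protein genes took 1.61% to 1.92% of the reads in listed genes in WT and 0.820% in the library labelled cKO.

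**Figure D3:**
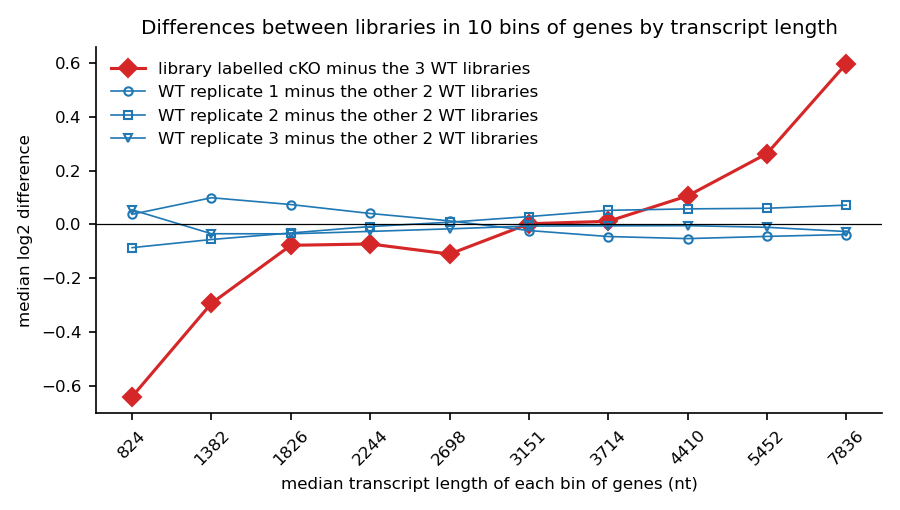
Median log2 difference (vertical axis) of genes in 10 equal bins by transcript length, labelled with the median length in nt. Diamonds are the library labelled cKO minus the 3 WT libraries, running from -0.64 to 0.60, and open symbols are each WT library minus the other 2, which stay between -0.09 and 0.10.

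Mitochondrially encoded genes split, with 4 of 10 higher and 5 lower, also adjusted over the list alone. The median was -0.34 and the mean -0.20, while the direction of the test was up (camera, Benjamini-Hochberg adjusted p = 0.837). The respiratory chain genes mt-Nd2 and mt-Nd6 rose 2.25-fold and 2.15-fold, mt-Atp6 fell 2.39-fold, and mt-Co3 went from 332 ± 226 (SD, n = 3) to 47.9, a call lost with a robust variance trend (adjusted p = 0.159 by limma with Benjamini-Hochberg adjustment). Cell cycle genes gave 6 higher and 15 lower of 26, also adjusted over the list alone (median -0.45; camera, Benjamini-Hochberg adjusted p = 0.115). Ccnb2 fell 4.84-fold, Birc5 4.43-fold, Stmn1 2.95-fold and Tyms 2.93-fold.

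Pathways in which ROR alpha is known to act were not called as lists. Of 17 clock genes 5 rose and 3 fell, also adjusted over the list alone, with a median of -0.011 and a mean of 0.13 (camera, up, Benjamini-Hochberg adjusted p = 0.617). Clock and Per2, core genes of the circadian oscillator, rose 2.31-fold and 2.17-fold and Nfil3 1.70-fold, and Bhlhe40 fell 2.05-fold from 58059 ± 7033 (SD, n = 3). Of 22 sterol and lipid synthesis genes 5 rose and 9 fell, also adjusted over the list alone, with a median of 0.069, a mean of -0.005 and the test down (camera, Benjamini-Hochberg adjusted p = 0.963). Ldlr, the low density lipoprotein receptor gene, rose 2.60-fold and Scd2 1.79-fold, and Cyp51 and Fdft1, enzymes of cholesterol synthesis, fell 1.90-fold and 1.63-fold. Of 19 fatty acid oxidation and PPAR genes 5 rose and 7 fell, also adjusted over the list alone (median -0.11; camera, Benjamini-Hochberg adjusted p = 0.450). Ppard and Ppargc1b rose 4.10-fold and 2.60-fold, and Hadha and Etfb, of mitochondrial fat oxidation, fell 2.33-fold and 2.08-fold.

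**Figure D4:**
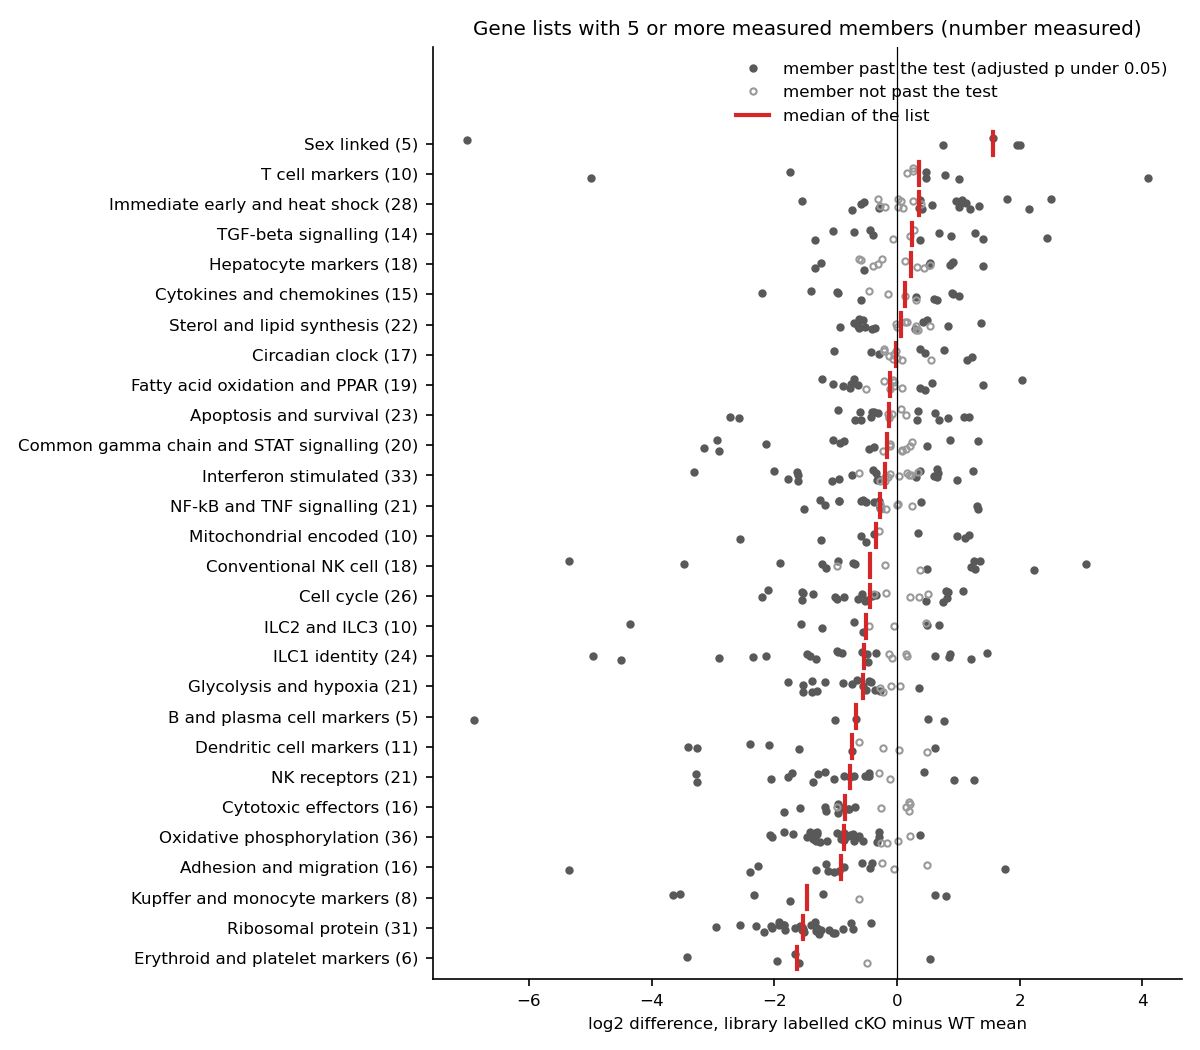
Log2 difference (horizontal axis, library labelled cKO minus WT mean) of each measured member of the 28 tested lists. Filled points passed the limma test, open points did not, and the red bar is the list's median. Erythroid (-1.63), ribosomal protein (-1.53) and Kupffer cell and monocyte (-1.47) medians are lowest, and the sex-linked list (1.57) is highest.

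Markers of other cell types, fixed beforehand as purity checks, moved in both directions, but each of these lists that was called was lower. Whether their changes arose in ILC1 or in other cells carried through the sort was not tested. Of 10 T cell markers 5 rose and 2 fell, also adjusted over the list alone (median 0.37; camera, Benjamini-Hochberg adjusted p = 0.379). Apart from Cd8a, the T cell receptor constant gene Trbc1 rose 2.01-fold, while its neighbour Trbc2 fell 3.33-fold and the costimulatory receptor Cd28 fell 32.5-fold, from 1418 ± 163 (SD, n = 3) to 43.6. The B and plasma cell list held 2 higher and 3 lower of 5, also adjusted over the list alone (median -0.66; camera, Benjamini-Hochberg adjusted p = 0.415), with Cd79a down 2.03-fold, Ighm down 1.58-fold and Cd79b up 1.69-fold. Of 8 Kupffer cell and monocyte markers 5 fell and 2 rose, also adjusted over the list alone (median -1.47). The complement genes C1qa, C1qb and C1qc fell 14.6-fold, 5.20-fold and 3.48-fold and the lysozyme gene Lyz2 11.8-fold. That list passed camera (Benjamini-Hochberg adjusted p = 0.0371; adjusted p = 0.591 with an estimated correlation) but not under 7 of the other settings, with adjusted p from 0.0515 to 0.113 there. Of 11 dendritic cell markers 6 fell and 1 rose, also adjusted over the list alone (median -0.73; camera, Benjamini-Hochberg adjusted p = 0.00560; adjusted p = 0.591 with an estimated correlation). The class II genes H2-Aa, H2-Ab1 and H2-Eb1, which present antigen, fell 10.7-fold, 9.66-fold and 4.29-fold, and Siglech fell 5.64-fold.

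Of 6 erythroid and platelet markers 4 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -1.63 (camera, Benjamini-Hochberg adjusted p = 0.00162; adjusted p = 0.591 with an estimated correlation). The haemoglobin genes Hbb-bt, Hba-a2, Hbb-bs and Hba-a1 fell 10.9-fold, 3.89-fold, 3.16-fold and 3.04-fold. They are close copies whose single values are uncertain. Of 18 hepatocyte markers 6 rose and 3 fell (5 and 3 adjusted over the list alone; median 0.22; camera, Benjamini-Hochberg adjusted p = 0.617). The fibrinogen genes Fga and Fgb rose 2.59-fold and 1.87-fold, Apoc1 fell 2.57-fold, and Cyp3a11 fell 2.47-fold, a call lost under quantile normalization (adjusted p = 0.212 by limma with Benjamini-Hochberg adjustment). Lists with too few measured members for a test were those of neutrophils and mast cells, with 1 of 2 lower (Mmp9, 14.7-fold), and of endothelial and stellate cells, whose only measured member Pecam1 fell 4.23-fold. These counts were the same adjusted over the list alone.

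Sex-linked genes differed between the groups. Xist, the RNA that silences an X chromosome in female cells, was at 131 ± 30.7 normalised counts in WT (SD, n = 3) and at 0 reads in the library labelled cKO. The Y-linked genes were read in all 4 libraries and were higher in the library labelled cKO, Kdm5d 4.03-fold, Eif2s3y 3.88-fold and Ddx3y 2.93-fold, and Uty, named after its value was seen, by 0.75 on the log2 scale. The list had 4 higher and 1 lower of 5, also adjusted over the list alone, with a median of 1.57, a mean of -0.15 and the test up (camera, Benjamini-Hochberg adjusted p = 0.0734). It passed without WT replicate 2 (adjusted p = 0.0175) and without WT replicate 3 (adjusted p = 0.0211).

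Each library was also set alone against the other 3. The library labelled cKO gave 6527 genes, and WT replicates 1, 2 and 3 gave 0 each by limma with Benjamini-Hochberg adjustment, with 8, 5 and 6 genes at an unadjusted p under 0.05. The library labelled cKO stands among the other 3 in these WT counts and widens their spread. Against the other 2 WT libraries only, WT replicates 1, 2 and 3 gave 12, 63 and 20 genes. Of the 28 lists tested, 11 were called with the preset correlation, 10 lower and 1 higher. With the estimated correlation 0 were called, and 1 list had an unadjusted p under 0.05. That test has 2 residual degrees of freedom and can call few lists. ILC1 identity lost its call there although its estimated correlation, 0.0016, was below the preset 0.01. All other called lists had estimates above the preset. These ran from 0.013 for glycolysis and hypoxia to 0.61 for ribosomal proteins and 0.63 for erythroid and platelet markers. For those lists the p-values at the preset assume less correlation than was estimated. Lists called lower, other than ILC1 identity, had medians at or below 4.52% of the random lists, and the list called higher at 100%. The cell cycle and sex-linked lists, not called, ranked at 0.96% and 99.96%.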

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

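The mean of at least 500, voom, the restriction to genes with a length, the removal of length and GC trends, the comparison of each WT library with the other 2 and the sign of the list medians were tests chosen after the results were seen; the other alternatives were fixed before the data were examined. No paired analysis was possible because the groups share only replicate number 1. The planned count test was not run, since the deposited values are not counts, and voom on the recovered reads, with 6832 genes called, stood in for it. The count of 6527 genes lay between 4356 and 6832 under the settings that kept all libraries, and between 6118 and 6520 with each WT library left out. No filter and a mean of at least 5 removed 0 genes and therefore tested nothing. With a mean of at least 500, which left out 4309 genes, 1797 genes were higher against 3151, as fewer genes were tested. Rora kept a small negative difference in most settings (-0.09 to -0.01 with each WT library left out) but was 0.017 under quantile normalization, and it became -0.72 with the length trend removed and -0.53 with length and GC trends removed, both past the threshold, as the correction lowers long transcripts. The number of lists called went from 11 to 0 with the estimated correlation, and the highest number of genes for a WT library went from 0 to 63 when the library labelled cKO was left out of the comparison. The test with the estimated correlation has only 2 residual degrees of freedom, so a lost call there does not show that correlation made the call. Nor does it show that correlation played no part, as the estimate for ribosomal proteins was 0.61. Of 2321 values of the 132 named genes other than Rora, 2319 kept direction and call, 2 lost the call (Cyp3a11 and mt-Co3) and 0 turned. These genes were chosen for the largest differences past the threshold in the main fit, so their calls were likely to hold. This total and the next, for the lists, include no filter and a mean of at least 5, which tested nothing. Of 500 values of 28 lists, 477 kept the direction of the test and the call, 9 lost the call, 3 gained it and in 11 the direction of the test turned. These 11 were in 3 lists never called, and in each of the 11 the median kept its sign, which was opposite to the direction of the main test. There the median of cytokines and chemokines was 0.29 under quantile normalization, 0.14 without the variance trend, 0.41 with length removed, 0.23 with length and GC removed and 0.10 without WT replicate 1 (0.10 to 0.16 with each WT library left out). That of sterol synthesis was 0.069 without the variance trend and 0.087 and 0.065 without WT replicates 2 and 3 (0.048 to 0.087 with each left out), and that of mitochondrially encoded genes -0.49 with GC removed and -0.49 and -0.31 without WT replicates 1 and 3 (-0.49 to -0.18 with each left out). In 11 other values, in 5 lists not called there, the median turned while the test kept its direction. The sterol median became -0.37 with a mean of at least 500, -0.12 with length removed and -0.098 with length and GC removed, and the mitochondrial one 0.34 with a mean of at least 500 and 0.21 with length removed. The clock median became 0.0043 under trimmed-mean scaling, 0.067 and 0.038 without WT replicates 2 and 3 and 0.016 with GC removed, that of apoptosis 0.040 under quantile normalization and that of TGF-beta -0.058 with length removed. The cause of these turns was not tested. Depth limits genes with few reads, since 3 reads in the library labelled cKO equal 2.14 normalised counts.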

Other observations

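The tests for conventional NK cells and for CD8 T cells were chosen after the result was seen, first on a few genes and then on whole lists, as was the comparison of histone genes with other RNAs without a tail, and the genes of the first 2 paragraphs were picked from the tables after their values were seen; the other tests below were set before their own result was seen.

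The share of genes that differed was also counted by position, without a test against chance. Among 344 windows of 5 Mb with at least 10 listed genes, where 21.4% of all genes differed 2-fold or more, the highest share was 70.0%, in the first 5 Mb of chromosome 13. There, 6 of the Akr1c and Akr1e reductase genes fell, among them Akr1c6 from 1128 to 375, Akr1c13 from 1712 to 709 and Akr1c14 from 74.2 to 9.98 normalised counts, although these close copies can exchange reads. Next came the window of chromosome 6 from 40000001 to 45000000, with 15 of 23 genes, which holds the T cell receptor beta locus. In it Trbj1-1 rose from 6174 to 22692 and Trbj1-2 from 1393 to 6317 next to Trbc1, while Trbj2-1 fell from 250 to 87.2 next to Trbc2 and Trbj2-6 rose from 39.5 to 88.6. Zyx, a gene of the actin cytoskeleton in the same window, rose from 14788 to 41683.

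Genes were also counted by transcript class, without a test between classes and without removing the length trend. Of 149 processed pseudogenes, 93 fell and 17 rose, with a median log2 difference of -0.95, and of 130 long intergenic noncoding RNAs 57 rose and 18 fell, with a median of 0.47. Rsrp1, which encodes a nuclear protein rich in arginine and serine, rose from 17572 to 95887, Ogt, the enzyme that attaches N-acetylglucosamine to proteins, from 1376 to 4132, and the splicing factor gene Srsf5 from 54533 to 91134. The linker histone gene Hist1h1c fell from 4184 to 1633. Rsrp1, Ogt and Srsf5 are also among the transcripts with introns that hold them in the nucleus tested below, and Hist1h1c among the histone genes. Their values are therefore not separate evidence.

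The 67 genes of ribosomal proteins and oxidative phosphorylation had a median log2 difference of -1.30 in the library labelled cKO. With the length trend removed it was -0.868 (95% bootstrap interval -1.01 to -0.75) and with the GC trend removed -1.29 (-1.44 to -1.02), so neither trend accounts for the whole pattern, although for oxidative phosphorylation alone the interval after the length correction, -0.85 to -0.38, passes the bound of -0.5 set for it. The bootstrap here and below resampled genes, not libraries. Its intervals therefore hold no spread between libraries and ignore that related genes can move together. Replication-dependent histone genes, whose RNA generally lacks a poly(A) tail, had a median of -0.832 (-1.42 to -0.66, n = 17), below the bound of 0 set beforehand to count against a less strict poly(A) selection in that library. With the length trend removed the histone median was -0.60 (-1.09 to -0.38). That bound cannot decide, because histone RNA also follows the cell cycle, of whose genes 15 of 26 fell and 6 rose. The cell cycle list was not called. It was also not tested whether the reads of these histone genes came from RNA without a tail. Small nuclear and small nucleolar RNAs, also without a tail, had medians of 1.38 (n = 6) and 0.82 (n = 5). Rn7sk, another nuclear RNA without a tail, stood at 0.20 (adjusted p = 0.280 by limma with Benjamini-Hochberg adjustment). A less strict poly(A) selection therefore stays open. A larger share of nuclear RNA may contribute, an idea prompted by the higher Neat1 and Malat1. For 10 other transcripts chosen for introns that hold them in the nucleus, the median was 0.818 (0.49 to 1.48) with the length trend removed. Before that removal their median was 0.95, and 9 of them were past the threshold and higher. Whether this came from handling or from the cells was not tested. With 1 library labelled cKO, a genotype effect stays open as well.

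Xist at 0 reads and higher Y-linked genes in the library labelled cKO may come from the sex of the mice, if the WT libraries held RNA of females and males and the library labelled cKO that of males. The X-linked genes that escape inactivation do not decide this. They had a median of 0.42 (range -1.26 to 0.78, n = 4), with Eif2s3x lower and Kdm6a and Kdm5c higher. Kdm5d, Eif2s3y, Ddx3y and Uty in WT stood at 24.8%, 25.8%, 34.1% and 59.5% of their level in the library labelled cKO. Reads of Xist (97.2 to 157 normalised counts) and of the Y-linked genes in every WT library are what RNA of both sexes would give. Sex and genotype cannot be told apart here, because these sex-linked genes differed between the groups and the labels give no sex.

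Cd8a and the Klra genes were higher while Klrb1c, Klrc1 and Ncr1 were lower in the library labelled cKO. Ncr1 may not belong to this pattern, since the Cre is driven from its locus, which was not tested. Of 18 conventional NK cell genes 7 rose and 8 fell, with a median of -0.439 (95% bootstrap interval -1.07 to 1.23); 7 of them picked after the result had a median of -1.22, yet Eomes rose from 91.6 to 231 and Itga2, which encodes the CD49b that the gate excludes, from 141 to 339. Of 10 T cell genes 5 rose and 2 fell, with a median of 0.365 (-0.74 to 0.78); 5 CD3 and receptor genes picked after the result had a median of 0.26, but Trbc1, left out there, rose from 63942 to 128626, while Cd28 fell 32.5-fold. A different haplotype around the NK gene complex, from 120270596 to 132386874 on chromosome 6, would be expected to alter other genes there. Of the 74 outside the Klr family, 13 differed 2-fold or more, 0.828 times the share elsewhere (odds ratio interval 0.398 to 1.46, Fisher exact p = 0.567). That region starts 2 Mb before Klrg1, and most of the 74 lie outside the stretch from Klrb1a to Klra1. Within that stretch only Gm156 and Gm23977, which directly precede Klra5, differed 2-fold or more, by 2.27 and 2.95 on the log2 scale. The share argues against a difference over the whole region but cannot decide on one limited to that stretch. Conventional NK cells and CD8 T cells, which the gate was set to remove by CD49b and CD3 and whose genes went both ways, stay open. So do a different receptor repertoire of the sorted ILC1, haplotype differences limited to that stretch or to the Klra genes, and the sex difference.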
